A study of Mus musculus with 6 samples.

How the data were processed

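DNA methylation was profiled in pancreatic tissue of 12-week-old mouse offspring by methylated DNA immunoprecipitation on tiling arrays (MeDIP-chip). In this assay an antibody pulls down methylated DNA fragments, and the pulled-down DNA is hybridised together with untreated genomic (input) DNA of the same sample. Per the labels' protocols, genomic DNA was extracted with a column kit, the immunoprecipitated DNA carried Cy5 and the input DNA carried Cy3. This orientation was the same on all 6 arrays, so a dye effect does not cancel within an array. The labels gave 3 arrays to offspring of dams with glucose intolerance and 3 to offspring of dams with normal glucose tolerance. The series text calls the first kind of dam hyperglycemic. The labels do not say whether the 3 samples of a group came from separate animals, dams or litters, so p-values measure the spread between these samples, which may be partly technical.

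Each array had 180465 spots, of which 5827 were control spots and were left out. The remaining 174638 probes were 45 to 60 nt long, each spotted once, with a median distance of 212 bp between neighbouring probe starts, and their coordinates were on mouse build mm9 per the file headers. Of these probes 167117 lay on autosomes, 7421 on chromosome X and 100 on chromosome Y. The deposited scanner files were made with Agilent Feature Extraction 11.0.1.1 and its ChIP protocol, per the file headers. They held spot intensity values for both dyes. The processed intensity values were background-subtracted and put on a common scale by a linear dye normalization, per the file headers. A log10 ratio of red over green was also given in the deposited scanner files and was used only as a check: it lay within 0.01 log2 units of the log2 ratio of the processed intensities for 96.7% of spots. The authors also deposited a series table on a log2 scale with the steps behind it not given in the sources used here. Its array medians lay between 0.027 and 0.038. Its region means correlated with the unsubtracted log2 Cy5 over Cy3 ratios of the same array at r = 0.994 to 0.999 across regions, which sets its direction as MeDIP over input. Neighbouring probes correlated at r = 0.731 to 0.773 in that table and at 0.222 to 0.317 in the scanner ratios. The table may therefore hold values smoothed along the genome, and other causes of this gap were not tested. Its background treatment, normalization and any smoothing stay unknown, and it was used as an alternative. No other column of per-sample values was left unmatched.

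The measurement was log2 of processed Cy5 over processed Cy3 intensity, centred on the median of all non-control probes of each array, without loess or quantile normalization. Spots marked as non-uniformity outliers (1.77% of spots) were set to missing. Probes whose input signal was not well above background on every array were left out, which removed 58723 probes (33.6%). Of all probes, 57789 had such a dim input spot on at least 1 array of the glucose intolerance group and 29652 on at least 1 array of the normal tolerance group. A region was a run of at least 3 of the kept probes on 1 chromosome with starts at most 500 bp apart, and its value was the mean over its probes. This gave 18562 regions with a median of 5 probes; 1 more region lacked a value on an array and was left out. In all, 115649 probes had enough values to be tested. The filter did not require MeDIP signal above background. Where MeDIP spots were not well above background, a second value is given with each such spot raised to the lowest processed MeDIP signal well above background on its array, if its own was lower. Differences of single channels were taken over the same spots as the ratios.

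Group differences are coded as glucose intolerance minus normal tolerance. They were tested per probe and per region with limma 3.58.1 (lmFit and eBayes, R 4.3.3) and Benjamini-Hochberg adjustment at 0.05. The regions to be named were the 3 with the lowest p in each direction. The tests, this rule and most alternatives were fixed before the data were examined. Promoter tests, gene list tests, and the comparison of germline with housekeeping promoters on each array had been planned too. They could not be run, because the scanner files pair probes with coordinates only, and the gene table used here is for build GRCm38.p6; no coordinates were converted and no gene is named. The rule for named genes therefore applied to regions alone. The location classes of the plan were replaced by chromosomes, the one annotation the scanner files give. Chromosome means, relative to the median region of the same array, were compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 arrays against 3. A test of called probes against classes was planned for 20 calls or more and was not run.

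The median-centred values left a shift between the groups among the tested regions. The median region difference was 0.12 log2 units, and 0.11 with no filter on dim or flagged spots. Differences are therefore also given beyond this shift where a region is named. A difference in the total methylation of the genome cannot be read from median-centred ratios.

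The scans show 3 slides. All arrays of the glucose intolerance group lay on slide 1, normal tolerance replicate 1 on slide 2, and normal tolerance replicates 2 and 3 on slide 3. The red photomultiplier was set to 359 V, 394 V and 421 V on slides 1, 2 and 3, and the green one to 356 V throughout. No slide held both groups, so no comparison of the groups within a slide could be made, and the slide was fitted as a random block (duplicateCorrelation, statmod 1.5.0).

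The fits were tested on simulated data with the measured means and moderated variances, in which 50 features were changed by each step size. Over 18562 simulated regions, 6% of those changed by 0.5 log2 units were called, 84% at 1 unit, 98% at 2 units and 100% at 3 units. Over 102221 simulated probes, 0% were called at 0.5 units, 6% at 1 unit, 78% at 2 units and 100% at 3 units. In these simulations 7 unchanged regions and 12 unchanged probes were called as well. In a simulation with nothing changed, 0 regions and 0 probes were called, and 4.6% of regions had an unadjusted p under 0.05 in limma. The simulated noise was normal and independent between arrays, while the measured regions had a correlation of 0.37 within slides. These shares therefore hold for the simulations and are not the power of the real design.

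Alternatives covered the background correction (normexp with offset 50, on median in place of mean signals because the scanner files used here hold the former), loess, scaling to a common spread and quantile normalization, the deposited series table, the spot filters, the autosomes alone, each array left out, the replicate number or the slide as a block, other variance models, array weights, an unmoderated test and other region gaps. Further ones on centring, on unsubtracted signals and on each spot filter alone were added after seeing the data. The number of arrays limits the precision. Plots were drawn with matplotlib from the same values.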

Results

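MeDIP-chip ratios were obtained from the pancreas of 12-week-old mouse offspring, 3 arrays from offspring of dams with glucose intolerance and 3 from offspring of dams with normal glucose tolerance. The series asks whether maternal hyperglycemia goes with altered DNA methylation in the pancreas of the offspring. A higher ratio of immunoprecipitated (MeDIP) over input DNA means more DNA pulled down by the antibody against methylated DNA relative to the input signal of the same probe, and it can come from either channel. Signal over background stood in for depth. The median background-subtracted input signal was 24.9, 27.5 and 41.9 units on glucose intolerance replicates 1, 2 and 3, against 93.8, 62.5 and 53.9 units on normal tolerance replicates 1, 2 and 3. The MeDIP signal ranged from 62.0 to 78.8 units in the first group and from 90.4 to 106.8 units in the second. The red photomultiplier was set lower for the first group (359 V against 394 V and 421 V), so these MeDIP values are not at the same gain. Input spots were well above background for 71.0%, 72.5% and 78.7% of probes in the glucose intolerance group and for 92.4%, 87.1% and 85.5% in the normal tolerance group. Across the 18562 tested regions, arrays correlated at r = 0.913 to 0.954 within the glucose intolerance group, at 0.894 to 0.924 within the normal tolerance group and at 0.783 to 0.947 between groups. These correlations are across regions, which are not independent replicates.

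At the level of regions, 112 of 18562 differed by more than 1 log2 unit between the groups, and 0 passed an adjusted p of 0.05 in limma. The lowest p among regions with a higher ratio in the offspring of glucose-intolerant dams belonged to 3 regions. On chromosome 11 at 57457938 to 57458587 (3 probes) the ratio was 0.95 ± 0.03 log2 units against 0.06 ± 0.06 with normal tolerance (SD, n = 3 each), a difference of 0.89 or 1.85-fold. On chromosome 9 at 55875180 to 55875853 (4 probes) it was -0.08 ± 0.19 against -1.16 ± 0.16, a difference of 1.08. On chromosome 17 at 19796606 to 19797550 (3 probes) it was -0.40 ± 0.31 against -1.66 ± 0.14, a difference of 1.26. Every probe of these 3 regions differed in the same direction, but by uneven amounts. On chromosome 11 the probe differences ran from 0.27 to 1.41 (median 0.34). They ran from 0.62 to 2.20 on chromosome 9 (median 0.75) and from 0.19 to 2.29 on chromosome 17 (median 1.29). Relative to the array median, input differed by -0.04, -0.64 and -0.48 log2 units in the chromosome 11, 9 and 17 regions, and MeDIP signal by 0.73, 0.32 and 0.65. On chromosome 9 more of the difference lay in a lower input signal than in a higher MeDIP signal, and on chromosome 17 part of it did. Channels and ratios were centred separately, so their differences do not add up exactly. Some MeDIP spots were not well above background. On chromosome 9 this left 10 of 12 spots with maternal glucose intolerance and 9 of 12 with normal tolerance, and on chromosome 17 it left 7 and 6 of 9. With dim MeDIP spots raised to the lowest signal well above background, the differences were 0.86 on chromosome 9 and 0.89 on chromosome 17. On chromosome 11 all MeDIP spots were above background and 2 of 9 normal tolerance spots were outliers and left out. The normal tolerance arrays so lacked some probes that the other group averaged, and part of the 0.89 can come from that. With these spots kept the normal tolerance mean was 0.31 and the difference there was 0.65. With probes of dim input kept instead, the region grew to 8 probes and the difference was 0.05; the chromosome 9 and 17 regions grew as well, to 8 and 7 probes, with differences of 0.68 and 0.64. With the authors' deposited values the differences were 0.16, 0.73 and 0.41. Beyond the median shift of 0.12, their differences were 0.77, 0.96 and 1.13.

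Among regions with a lower ratio with maternal glucose intolerance, the lowest p belonged to a region on chromosome 1 at 163061326 to 163062033 (3 probes), at -0.57 ± 0.13 against 0.41 ± 0.04, a difference of -0.98 log2 units (SD, n = 3 each). On chromosome 17 at 71198643 to 71200179 the mean of 7 probes was -0.37 ± 0.03 against 0.40 ± 0.13, a difference of -0.77. All 7 probes were lower, with differences from -2.04 to -0.02. On chromosome 1 at 121545078 to 121546845 (5 probes) the ratio was -0.78 ± 0.06 against 0.06 ± 0.19, a difference of -0.84, with 3 of the 5 probes lower. Beyond the median shift these differences were -1.10, -0.89 and -0.96. Here the MeDIP signal differed by -1.16, -0.61 and -0.83 log2 units relative to the array median and the input signal by -0.06, 0.29 and 0.13. MeDIP spots were well above background on 6 of 9, 19 of 21 and 13 of 15 spots with maternal glucose intolerance and on all with normal tolerance. With dim spots raised as above, the differences were -0.64, -0.70 and -0.77. With probes of dim input kept, they were -0.66, -0.22 and -0.51 over 8, 25 and 7 probes. With the authors' deposited values the ratios differed by -0.48, -0.47 and -0.58. In all 6 named regions the 3 arrays of one group lay on the same side of the 3 arrays of the other. Their adjusted p from limma was 0.168 in each case, so none passed.

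**Figure D1:**
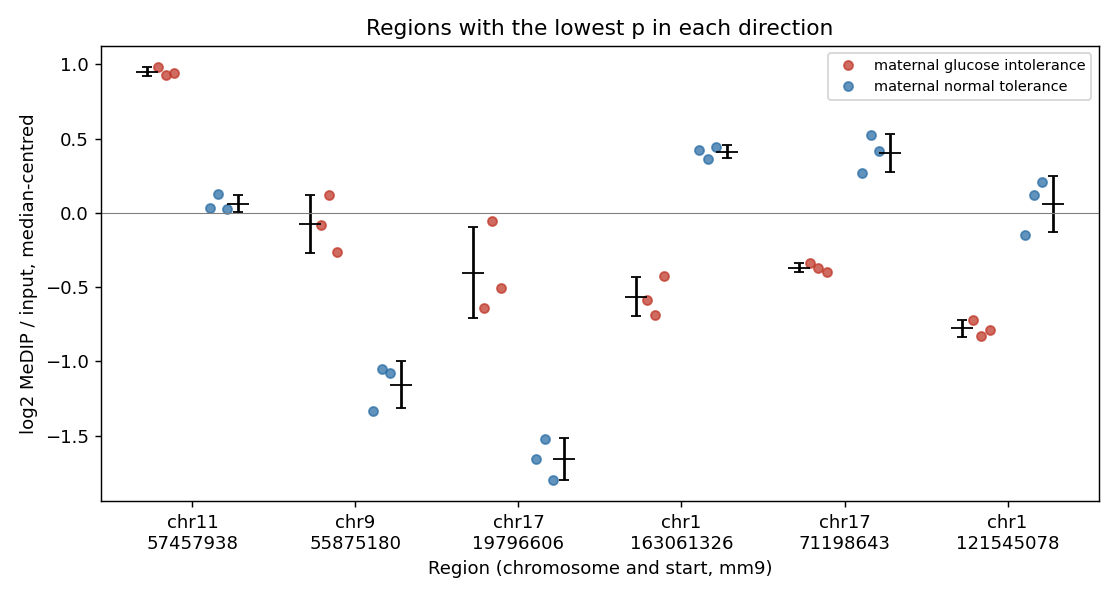
MeDIP over input ratio (log2, centred on each array's median) on each array in the 6 named regions, by chromosome and mm9 start. Points are arrays, red for maternal glucose intolerance and blue for normal tolerance, and bars are the mean ± SD of 3 arrays; the groups do not overlap in any of these regions, and none passed the adjusted threshold (adjusted p 0.168).

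An unadjusted p under 0.05 was reached by 2934 regions (15.8%), of which 2468 (84.1%) were higher and 466 lower in the glucose intolerance group. This count moved to 5157 without normal tolerance replicate 1, to 1561 without normal tolerance replicate 3, to 1682 without glucose intolerance replicate 2 and to 1907 without glucose intolerance replicate 3. Normal tolerance replicate 1 was the only array of slide 2. Without it each group lay on a single slide, and the error held no spread between slides. The share of higher regions varied with the processing. Of regions at that p, 52.7% were higher when arrays were centred on the tested regions, 45.1% after loess, 56.0% after quantile normalization and 97.2% after normexp background correction. Groups did not overlap in 22.1% of regions (3254 regions higher and 845 lower). Chance gives 10% for 3 arrays against 3 only if arrays are independent and the groups share no overall shift. Here regions had a correlation of 0.37 within slides, no slide held both groups, and a median shift of 0.12 log2 units remained. The 22.1% can therefore not be set against 10%. The adjusted count of 0 did not hold under some settings: 1516 regions passed with the authors' deposited values, 1616 with normexp, 172 with array weights and 76 with a trended robust variance. With the replicate number as a block 793 passed, but the numbers were not taken to pair the samples. With the slide as a random block 0 regions passed, and the count at an unadjusted p under 0.05 was 967 (5.2%). This block widens the error of the group difference, since no slide held both groups, so a share near 5% is no sign of chance.

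Of 115649 probes tested singly, 1 passed the adjusted threshold in limma (adjusted p 0.0412). It was probe Ch_220697_0077343 on chromosome 1 at 163061974 to 163062033, inside the region named above, and it was lower with maternal glucose intolerance on each of the 3 arrays. Its ratio was -2.74 ± 0.16 log2 units against 0.23 ± 0.17 (SD, n = 3 each), a measured difference of -2.97 with a standard error of 0.21. Its MeDIP signal was not well above background on any of the 3 glucose intolerance arrays and was so on all 3 normal tolerance arrays. With these dim spots raised to the lowest MeDIP signal well above background on their array, the ratio was 3.88-fold lower, a difference of -1.96. Its input signal differed by -0.49 log2 units relative to the array median. The other probes of that region, at 163061326 and 163061567, differed by -0.29 and 0.33, so the region's difference rested on this probe. At an unadjusted p under 0.05 there were 18271 probes, 11883 of them higher (65.0%) and 6388 lower. This count ran from 10246 to 32727 with 1 array left out, and was 6028 (5.2%) with the slide as a random block. The share of higher probes was 46.0% after loess, 50.8% with centring on the tested probes and 84.3% with normexp. The call was lost with the slide as a random block (adjusted p 0.564) and on leaving out any array other than normal tolerance replicate 1, while the difference stayed at -2.95 with the slide block and between -2.88 and -3.07 with an array left out. It was smaller with normexp (-0.95) and with the authors' deposited values (-1.23). Without normal tolerance replicate 1, 3780 probes passed, 1852 of them higher, and without any other single array 0 passed. Leaving out that array sets slide 1 against slide 3, so the error holds only the spread within slides. The 3780 therefore do not show that this array hid differences between the groups.

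Chromosome means were set against each other between groups only, since probes of different chromosomes have levels that depend on the probes themselves. The mean ratio of chromosome 7, relative to the array median, was -0.32 ± 0.10 log2 units with maternal glucose intolerance and -0.39 ± 0.07 with normal tolerance (SD, n = 3 each; 1678 regions). Chromosome 18 was at 0.00 ± 0.03 and -0.02 ± 0.04, and chromosome 15 at 0.00 ± 0.01 and -0.02 ± 0.01. Chromosome X was at -0.17 ± 0.05 and -0.20 ± 0.04, and the 8 regions of chromosome Y were at -0.78 ± 0.12 and -0.74 ± 0.15. Over 19 autosomes the difference ranged from 0.01 to 0.07 log2 units. The exact two-sided permutation test gave its smallest possible p of 0.1 for chromosomes 8, 12 and 15, each slightly higher with maternal glucose intolerance, and the lowest adjusted p over 21 chromosomes was 0.663. The share of regions at an unadjusted p under 0.05 was at most 17.9% on chromosomes other than Y.

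**Figure D2:**
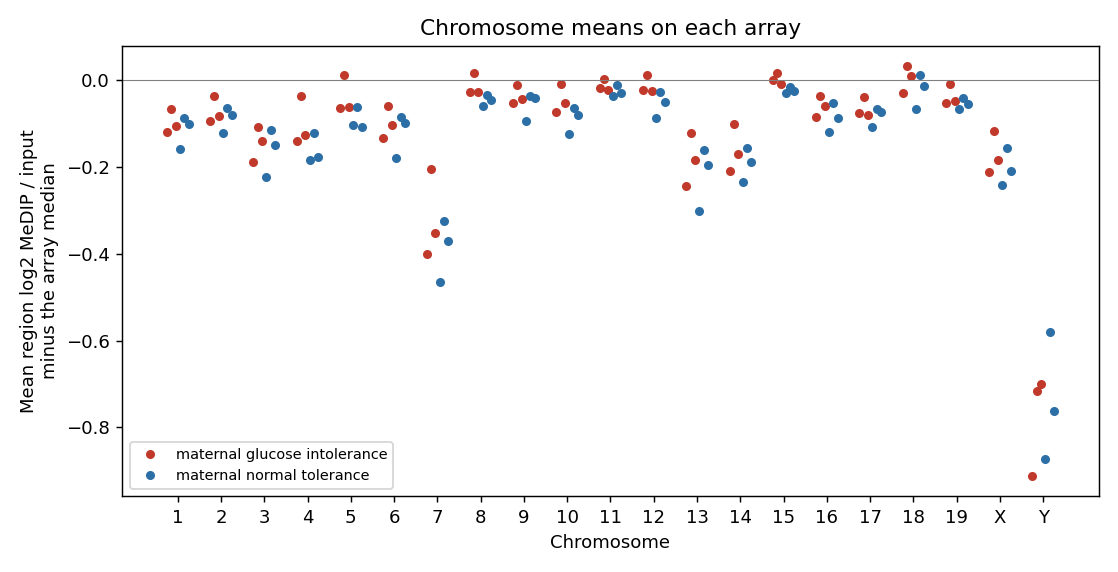
Mean region ratio of MeDIP over input (log2, minus the array's median region) by chromosome, 1 point per array, red for maternal glucose intolerance and blue for normal tolerance. The groups overlap on most chromosomes, and differ by 0.01 to 0.07 log2 units in their means over autosomes; heights of different chromosomes come from different probes and are not comparable.

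The input channel was compared between sex chromosomes and autosomes, since the labels give no sex. The median log2 input signal of chromosome X probes minus that of autosomal probes was -0.36, -0.35 and -0.37 on glucose intolerance replicates 1, 2 and 3 and -0.46, -0.34 and -0.37 on normal tolerance replicates 1, 2 and 3. For chromosome Y probes the values were -0.63, -0.58 and -0.76 against -0.57, -0.68 and -0.69. The groups overlapped in both values, and no array of known sex was there for reference.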

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

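The region count at an adjusted p of 0.05 stayed at 0 under 12 of the 22 other settings (arrays left out aside) and rose under the rest; the probe count stayed at 1 with autosomes alone and with outlier spots kept. The settings on unsubtracted signals, on centring and on each filter alone were chosen after seeing the data. The cause was not tested.

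Normexp gave 1616 regions and 6102 probes, the authors' processed values 1516 and 6272, array weights 172 and 6769, trended robust variances 76 and 747, and both channels above background 1 and 214. Quantile normalization gave 1685 probes and 0 regions. Unsubtracted signals gave 13 regions and 880 probes, with quantile normalization added 759 and 6803, and with a running mean over 3 probes as well 1269 and 9289. For regions these added steps bring the count towards that of the deposited table, while for probes the running mean moves it away. Centred on the tested regions, the deposited table gave 248 regions, 125 of them higher. The probe count fell to 0 with loess, scaling to a common spread, no filter, dim input kept, the slide as a random block, the unmoderated test and centring on the tested probes. Leaving out each array in turn gave 0 regions and 0 to 3780 probes. The 3780 came without normal tolerance replicate 1, where each group lay on a single slide.

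With the replicate number as a block, 793 regions and 4083 probes passed. Same-numbered arrays deviated together at r = 0.57, 0.54 and 0.04 across regions, so the numbers were not taken to pair the samples. In these deviations every glucose intolerance array correlated best with its own number, for replicate 3 by 0.04 against 0.02 for the next.

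The median region shift of 0.12 log2 units became 0.17 with normexp, 0.19 with unsubtracted signals, 0.069 with these, quantile normalization and smoothing, 0.097 with the deposited table, 0.0058 with that table centred on the tested regions, 0.036 with quantile normalization, -0.0034 with loess and 0.027 with centring on the tested regions. The X minus autosome difference of -0.0013 moved to -0.064 with no filter and -0.065 with dim input kept. The difference of chromosome 7 from the other autosomes, 0.04, moved by less than the spread between arrays, but its sign turned with both channels above background (-0.014) and without glucose intolerance replicate 2 (-0.0011).

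In the 6 named regions no sign turned, and 43 of 162 pairs of region and setting passed the adjusted threshold, but sizes moved widely. The chromosome 11 difference of 0.89 was 0.03 with no filter, 0.05 with dim input kept (8 probes), 0.65 with outlier spots kept and 0.0033 (adjusted p 0.986) with smoothed quantile-normalized unsubtracted signals. The chromosome 17 region at 19796606 went from 1.26 to 0.16 under that last setting, and the one at 71198643 from -0.77 to -0.19 with a gap of 1000 bp. The called probe was left out with both channels above background, was lower in 24 other settings and passed in 12 (adjusted p 0.0048 to 0.564). Promoter, gene list and germline enrichment alternatives were not run because no gene was named.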

Other observations

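The tests of other splits of the arrays were chosen after the results were seen; those on input brightness, slide, neighbouring probes and spot position were set beforehand.

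Among the 20 regions with the lowest p, 16 were higher and 4 lower with maternal glucose intolerance. The direction balance depends on the scaling: with the authors' values 1361 regions passed as higher and 155 as lower, and 125 and 123 when centred on the tested regions. A pair on chromosome 9 lay close together, at 55875180 to 55875853 and at 55888892 to 55890024, with differences of 1.08 and 0.81 (adjusted p 0.168 for each in limma). The pair was singled out after its values were seen. Relative to the array median, MeDIP signal differed by 0.32 and 0.49 log2 units there and input by -0.64 and -0.20.

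In the limma fit without a slide term, regions at an unadjusted p under 0.05 were more frequent than the 5% that chance gives on average, at 15.8%. With the slide as a random block their share was 5.2%, and 85.5% of these regions were higher. No slide held both groups, so a positive correlation within slides widens the error of the group differences. The lower share therefore does not show whether the excess came from the slide, the group or chance. A dim input is argued against as the whole cause: in the third of regions with the brightest input the share was 16.5%, and 12.0% after centring on the tested regions, where a dim input as the cause predicts a share near 5%. The slide cannot be told apart from the group, since no slide held both. Between slides 2 and 3, both of normal tolerance, region values of 1 array against 2 differed with an SD of 0.42 log2 units. The SD between the 2 arrays within slide 3 was 0.27. Neither can be set against the 0.26 of the group difference, which averages 3 arrays on each side. Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave as many regions, with 2934 against 2633 in the highest other; 10 splits are too few for a share under 0.05. Maternal glucose intolerance stays open as an explanation and was not tested apart from the slide.

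For regions past the adjusted threshold the real split and the highest other gave 0. A count of 0 is matched by all 10 splits whatever the data, so this comparison says nothing. For probes the real split gave 1 and the highest other 0, so 1 of 10 did, and 10 splits are too few for a share under 0.05.

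In 313 probes the 3 arrays of one group lay more than 1 log2 unit from the 3 of the other, 181 higher and 132 lower with maternal glucose intolerance. In 67 of them the MeDIP signal of the lower group was not well above background on any array, so the size of the gap is not measured there. These probes were not clustered on the arrays: 64 pairs of them lay within 10 rows and 5 columns of each other, against a median of 62 in 1000 random draws. This says little about a defect at 1 place on a slide. Each of these probes needs all 3 arrays of both groups apart, which a defect on 1 array could hardly give. A signal local to the probe stays open. Beyond the median shift, the nearest tested probe within 300 bp moved in the same direction by a median of 0.12 log2 units. The 95% bootstrap interval was 0.0064 to 0.21 (230 probes). The median was 1.75 for the probes themselves, and 57.0% of these neighbours moved the same way. The interval reaches both sides of the 0.1 below which a local signal was predicted. In the direction of the step, MeDIP signal of the step probes moved by a median of 1.14 log2 units and input signal by -0.61. These medians go opposite ways, which argues against a sequence variant that weakens both channels alike as the general cause. The probes were chosen by their ratio, so single probes may differ. Of the 10 splits, 2 (the real one included) gave as many such probes, and the highest other, with 366, set glucose intolerance replicate 1 and normal tolerance replicates 1 and 3 against the rest, which follows neither group nor slide. It keeps both replicate 1 arrays on one side and both replicate 2 arrays on the other, as does the split with 2633 regions above. Same-numbered arrays of these numbers deviated together at r = 0.57 and 0.54 across regions, but those of replicate 3 at 0.04. Both splits also follow the spread of region ratios on each array. Its SD was 0.85 and 0.93 log2 units on replicate 1 of glucose intolerance and normal tolerance. It was 0.706 on replicate 3 of each group, and 0.58 and 0.64 on replicate 2. Number and spread cannot be told apart here.

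Adjacent regions 10 to 50 kb apart differed together at r = 0.147 over 6854 pairs. Of the 10 splits 7 gave as high a value, up to 0.351, so the real split does not stand out.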
